A study of Mus musculus with 44 samples.

How the data were processed

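Total RNA of adult mouse liver, extracted with a Qiagen miRNeasy kit and made into libraries with the TruSeq Stranded Total RNA kit per the labels, was sequenced in 44 libraries. The labels gave the molecule as genomic DNA, although the protocol described RNA. For each library the authors deposited whole-number counts per gene symbol, with 23338 symbols in each table and 0 entries for unassigned reads. The genome build was mm10, and TopHat2 2.0.4, Bowtie2 2.1.0, SAMtools 0.1.18, Picard and HTSeq were named in the submitters' processing notes, which did not give the annotation, the strand setting or the handling of reads that map to several places.

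Groups were formed from sex and diet in the labels: 12 control females, 12 PR females, 9 control males and 11 PR males. Sample numbers fell into 10 runs of neighbouring numbers, defined from the labels before the counts were seen. A new run began where numbers skipped by more than 3, where the diet changed or where a sex came back, so that each run held a single diet was partly by definition. Diet could not be compared within a run, and litter was not stated. Totals of 986261 to 4984490 counts per library, with a biological coefficient of variation of 0.143, set the precision. All 223 pairs of libraries within groups were checked for duplicates, with chi-square per degree of freedom between 1.87 and 15.5. The 10889 genes kept by edgeR's filter were normalised by TMM, where CPM is the count scaled to a common library total, and were fitted with edgeR's robust quasi-likelihood model with a mean for each of the 4 groups (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Contrasts were diet in females, diet in males, their average, their difference and sex in controls, with sex in PR mice added after the data were seen. Benjamini-Hochberg adjusted p under 0.05 was the threshold, errors of log2 changes are standard errors and those of CPM are standard deviations.

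Before the data were examined, 35 gene lists were written from general knowledge of liver biology, and the 29 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry with the number run as a random block (consensus correlation 0.0666). The ribosomal RNA list (0 of 7 symbols listed) and the markers of cholangiocytes (4 tested), lymphocytes (0), red cells (1), fat tissue (2) and pancreas (1) had too few. Genes named in the text were chosen by a rule set beforehand: the 10 higher and 10 lower genes with the smallest p that passed, or the 10 with the smallest p where fewer than 5 passed; up to 4 members with the smallest p of each list that camera called; the 2 leading members of ribosome, amino acid and urea cycle lists; and the sex-linked genes. The 4 clock genes, Meg3 and the lists' members that passed over the list alone were named after their values were seen. Of the symbols, 20953 matched GENCODE vM21, the source of coordinates.

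The model was tested on simulated data with 50 genes changed at each size. At 1.25-fold, 1.5-fold, 2-fold and 3-fold it recovered 36%, 70%, 92% and 96% of them between females and 28%, 64%, 96% and 100% between males. All sizes were changed in the same simulated data, where 9 unchanged genes were called between females and 12 between males. Counts were drawn gene by gene with no effect of number run. A change confined to few genes would face a stricter threshold, so these shares need not hold for the diet comparisons. Alternatives were DESeq2 1.42.0, limma-voom with and without the run as a random block, other size factors and filters, counts summed per run and sex, leaving out each run, fits of only the groups compared, and 2 surrogate variables (sva 3.50.0). Library totals were compared with permutation tests (Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6), exact in males and with 100000 resamples in females, and plots were drawn with matplotlib 3.10.9. Diet labels were shuffled within sex in 60 splits, the real one included.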

Results

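Liver RNA of adult C57BL/6 mice was sequenced in 44 libraries. They came from a study of how the diet of one generation bears on the next, with ribosomal DNA as its theme. The labels gave each library a sex, a diet (control or protein restricted, PR), a generation (G2) and a sample number. There were 12 control females, 12 PR females, 9 control males and 11 PR males. The labels did not state which generation ate the restricted diet, at what age or for how long, nor which mice shared a litter. The p-values therefore measured the spread between these libraries. Read counts assigned to genes totalled 986261 to 4984490 per library (median 2688244), and 12777 to 14486 genes had at least 1 count. Of the gene symbols listed, 10889 were abundant enough to be tested, and these held 99.7% of all counts. Hepatocyte transcripts led: Alb (albumin) took 2.31% of all counts, Apob (apolipoprotein B) 1.56% and Trf (transferrin) 1.37%. None of the 7 ribosomal RNA symbols looked for was among the listed symbols, so the level of ribosomal RNA itself was not analysed here.

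The sex-linked transcripts matched the labelled sex in all 44 libraries. Xist, the RNA that silences an X chromosome in females (chromosome X, 103460366 to 103483254), stood at 636 ± 257.7 CPM in control females and 683 ± 264.4 CPM in PR females (mean ± SD, n = 12 each). It stood at 0.354 ± 0.313 CPM (n = 9) and 0.909 ± 1.37 CPM (n = 11) in control and PR males. Ddx3y, an RNA helicase gene of the Y chromosome, stood at 167 ± 22.4 CPM in control males and 177.5 ± 14.5 CPM in PR males. Kdm5d, Eif2s3y and Uty, also on the Y chromosome, stood at 38.2 ± 5.39 CPM, 81.9 ± 7.93 CPM and 52.1 ± 4.99 CPM in control males. In females the highest counts of these Y-linked genes in any library were 2 for Ddx3y, 3 for Eif2s3y, 1 for Uty and 1 for Kdm5d. Total counts were 2481010 ± 475002 in PR females and 2416670 ± 564469 in control females (SD; 2-sided permutation test, p = 0.765). In males they were 3150140 ± 1188080 and 2824770 ± 1091570 (exact permutation test, p = 0.531). The 10 most abundant genes took 10.8% of counts in PR females against 11.01% in control females (permutation p = 0.419), and 9.76% against 9.82% in males (exact permutation p = 0.823). The adjusted p over these 4 comparisons was 0.823 in each.

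The first comparison asked which liver transcripts differed between PR and control females. No transcript rose or fell past the test over all genes. The smallest p-value was that of Nipal3. Nipal3 (chromosome 4, 135445420 to 135495038) measured 12.04 ± 1.87 CPM in controls and 15.6 ± 2.13 CPM in PR females (SD, n = 12 each), a log2 change of 0.37 ± 0.094 (SE, p = 0.00031). Shmt2, the mitochondrial serine hydroxymethyltransferase that feeds one-carbon metabolism (chromosome 10, 127517123 to 127522444), measured 136 ± 15.1 CPM and 154 ± 10.1 CPM (log2 change 0.18 ± 0.053, p = 0.000972). Ubxn2a was at 49.5 ± 5.55 CPM and 41.1 ± 5.92 CPM, a log2 change of -0.27 ± 0.073. Cdk14, a cyclin-dependent kinase, was at 3.78 ± 1.13 CPM and 5.72 ± 1.06 CPM (log2 change 0.58 ± 0.15). Serpina4-ps1, a serpin pseudogene whose reads may be shared with its relatives, had the widest spread of these, 34.6 ± 40.7 CPM in controls and 7.14 ± 8.05 CPM in PR females (log2 change -2.33 ± 0.64, p = 0.000774). Over all genes edgeR's quasi-likelihood test called 0 of 10889 genes, and 357 had an unadjusted p under 0.05 where chance gives 544. DESeq2 and limma-voom also called 0, with 318 and 371. The 95% confidence interval of the change lay within 1.5-fold in either direction for 90.6% of the tested genes. Such intervals, here and in the comparisons below, took the libraries as independent. They made no allowance for number runs, within which diet did not vary, and may be too narrow.

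Of 29 gene lists fixed before the data were examined, 9 passed camera with its preset correlation in females. Of these, 6 had higher and 3 had lower members in PR mice, and 0 passed with an estimated correlation. The highest were the markers of pericentral hepatocytes (14 of 15 members above zero, median 0.16, adjusted p = 1.93e-06, and adjusted p = 0.104 with an estimated correlation). Cyp1a2, a drug-metabolising cytochrome P450, led them (394 ± 87.4 CPM in controls, 505 ± 129 CPM in PR females, log2 change 0.36 ± 0.12). Next were Gulo, of vitamin C synthesis (0.16 ± 0.060), Rhbg, an ammonium transporter (0.40 ± 0.16), and Oat, ornithine aminotransferase (0.33 ± 0.14). Members also lay higher in the list of the interferon response (20 of 23 members above zero, median 0.15, adjusted p = 0.0008, and adjusted p = 0.609 with an estimated correlation). Leading members were Ifih1, a sensor of viral RNA (0.15 ± 0.070), Oasl1 (0.37 ± 0.17) and Usp18 (0.31 ± 0.14). Higher medians were also seen for xenobiotic metabolism (18 of 25 members above zero, median 0.12, adjusted p = 0.00296, and adjusted p = 0.609 with an estimated correlation), with Gstm2 at 0.25 ± 0.14 and Aldh1a1 at 0.21 ± 0.13. The same held for targets of PPAR alpha (25 of 27 members above zero, median 0.069, adjusted p = 0.0008, and adjusted p = 0.675 with an estimated correlation). Among these was Acaa1a, of peroxisomal fatty acid oxidation (0.18 ± 0.087). Small positive medians were found for the urea cycle and amino acid catabolism (26 of 31 members above zero, median 0.055, adjusted p = 0.00130, and adjusted p = 0.675 with an estimated correlation). Prodh (0.27 ± 0.14) and Hgd (0.12 ± 0.067) lay above zero and Sdsl (-0.43 ± 0.20) below it. Oxidative phosphorylation had one too, shown by 37 of 47 members above zero (median 0.020, adjusted p = 0.0240, and adjusted p = 0.902 with an estimated correlation).

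On the lower side in PR females were cytosolic ribosomal proteins (68 of 73 members below zero, median -0.059, adjusted p = 2.11e-07, and adjusted p = 0.682 with an estimated correlation). Rps7 measured 218.96 ± 26.2 CPM in controls and 203.2 ± 21.6 CPM in PR females (log2 change -0.11 ± 0.062). The list of RNA polymerase I and ribosome biogenesis, which bears on ribosomal RNA synthesis, had lower values: 29 of 36 members below zero, median -0.072, adjusted p = 0.00555, and adjusted p = 0.609 with an estimated correlation. Its leading members were Mybbp1a (-0.17 ± 0.086) and Nhp2 (-0.20 ± 0.11), with the nucleolar protein gene Npm1 at -0.10 ± 0.063. Genes of endoplasmic reticulum stress lay lower as well: 17 of 19 members below zero, median -0.10, adjusted p = 0.0008, and adjusted p = 0.682 with an estimated correlation. Xbp1, a transcription factor of that response, was at -0.21 ± 0.11 and the chaperone gene Hyou1 at -0.36 ± 0.19. No member of any of these lists passed over all genes. Adjusted over the list alone, 1 of 17 amino acid deprivation genes passed, Shmt2 (adjusted p = 0.0165). So did 1 of 12 imprinted genes, Meg3, a maternally expressed non-coding RNA (log2 change 1.06 ± 0.34, adjusted p = 0.0338). This adjustment was made within each list and did not correct for the 29 lists examined, so some such passes can arise by chance. Counts of lists this high were common when diet labels were shuffled within sex, with 15 of 60 splits, the real one included, giving at least 9. In the females of number runs 1, 2, 3 and 5 and in those of runs 4, 8, 9 and 10, medians were 0.19 and 0.14 for pericentral markers and -0.068 and -0.038 for ribosomal proteins. They were 0.25 and -0.065 for PPAR alpha targets, -0.045 and 0.18 for the urea cycle list, -0.0062 and 0.061 for oxidative phosphorylation, 0.017 and 0.082 for xenobiotic metabolism and 0.018 and -0.26 for endoplasmic reticulum stress. Without number run 1 (3 control females) the ribosomal protein median was -0.0038, and 3 lists passed camera, while without number run 10 (3 control females) the oxidative phosphorylation median was -0.021.

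In males, the same question gave no transcript that rose or fell in PR mice (n = 11) against controls (n = 9) past the test over all genes. The nearest was Rfc3, a subunit of the clamp loader of DNA replication (chromosome 5, 151642756 to 151651242), at 5.48 ± 1.44 CPM in controls and 9.05 ± 2.26 CPM in PR males (SD), a log2 change of 0.71 ± 0.16 (SE, Benjamini-Hochberg adjusted p = 0.472 by edgeR). Trp53i11 (9.03 ± 1.15 CPM and 5.75 ± 1.27 CPM) and Gata6, a transcription factor gene (7.20 ± 1.54 CPM and 4.52 ± 1.26 CPM), had lower means in PR males. Il6ra, the interleukin-6 receptor alpha chain, measured 44.3 ± 19.5 CPM and 27.2 ± 7.27 CPM (log2 change -0.71 ± 0.21), and Jun, an early-response transcription factor, 11.98 ± 4.49 CPM and 26.6 ± 15.7 CPM (1.21 ± 0.36). Over all genes edgeR's quasi-likelihood test called 0 of 10889 genes, and 434 had an unadjusted p under 0.05 where chance gives 544. DESeq2 and limma-voom also called 0, with 418 and 436. Without number run 9, which held 3 of the control males and 3 control females, 1 gene passed: Acss3, a mitochondrial short-chain acyl-CoA synthetase (log2 change 0.91, adjusted p = 0.0480 by edgeR). The 95% interval lay within 1.5-fold for 87.2% of genes.

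Fatty acid and triglyceride synthesis was the list that stood out in PR males. All 23 tested members lay above zero, the median log2 change was 0.30, and camera gave an adjusted p of 3.24e-11 (adjusted p = 0.414 with an estimated correlation). Thrsp, a regulator of lipogenesis, measured 255.3 ± 113 CPM in controls and 521 ± 362 CPM in PR males (log2 change 1.02 ± 0.36). Elovl6, a fatty acid elongase, measured 147 ± 27.4 CPM and 266 ± 205.8 CPM (0.86 ± 0.30). Fasn, fatty acid synthase, measured 833 ± 331 CPM and 1338 ± 733 CPM (0.68 ± 0.29), and Acly, which makes cytosolic acetyl-CoA, 523 ± 128 CPM and 763 ± 401 CPM (0.54 ± 0.23). Of the members, 10 had an unadjusted p under 0.05, 0 passed over all genes and 0 when adjusted over the list alone. In PR females the list had a median of 0.032 (camera, adjusted p = 0.975).

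Genes of cholesterol synthesis and uptake also had higher values in PR males, 22 of 25 members above zero, median 0.11, adjusted p = 0.00159, and adjusted p = 0.699 with an estimated correlation. Stard4, a sterol carrier gene, was at 0.22 ± 0.11 and Acat2 at 0.22 ± 0.14. The nuclear-encoded genes of oxidative phosphorylation had 42 of 47 members above zero, median 0.053, adjusted p = 9.69e-06, and adjusted p = 0.699 with an estimated correlation. Cox5a was at 0.13 ± 0.058 and Cox6a1 at 0.12 ± 0.052. Acute phase genes lay lower, 17 of 24 members below zero, median -0.13, adjusted p = 0.0271, and adjusted p = 0.699 with an estimated correlation. Among them were the 3 fibrinogen chains Fga (4685 ± 961 CPM and 4138 ± 305 CPM, log2 change -0.18 ± 0.080), Fgb (-0.16 ± 0.075) and Fgg (-0.15 ± 0.081). Without number run 5 (3 control males, 3 control females) the acute phase median was 0.084, on the other side of zero. The list of female-biased liver genes had 17 of 22 members above zero (adjusted p = 0.00196, and adjusted p = 0.699 with an estimated correlation), but 6 of them had 3 or fewer counts in all libraries of a male group together. Its median was 0.49 over all members and 0.38 over the 16 with more counts than that. The call depended on 1 library, PR male 240: without it, a choice made after the data were seen, the median of the list was 0.27 and it no longer passed. That library also held 22 counts of Xist, against 3 at most in control males. Of the 22 members, 11 had their highest level among PR males in it (Cyp2b9 with 11.6 CPM, against at most 2.36 in other PR males and 4.11 in control males). Another PR male was higher for 11 (Cyp2c40 with 9.36 CPM, against 3.87), so whether the library held female RNA was left open. The acute phase list did not pass without PR male 240 either (median -0.15), and the cholesterol median was 0.070 without that library. Cyp2b9, a female-biased cytochrome P450, stood at 0.955 ± 1.44 CPM in control and 2.09 ± 3.25 CPM in PR males, against 599 ± 96.5 CPM in control females. Adam11 stood at 4.15 ± 1.65 CPM and 6.68 ± 2.07 CPM in control and PR males, against 2.58 CPM in control females. This member of the list was thus higher in males, and its higher level in PR males was not a move toward the female level. Altogether 5 of 29 lists passed camera and 0 with an estimated correlation. Counting the real labels among them, 47 of 60 label shuffles gave at least 5. Among lists that did not pass, ribosomal proteins had a median of -0.017, RNA polymerase I and ribosome biogenesis 0.041 and the amino acid deprivation response 0.055. Leading members of the last were Vldlr (0.90 ± 0.38) and Atf4 (0.17 ± 0.080).

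**Figure D1:**
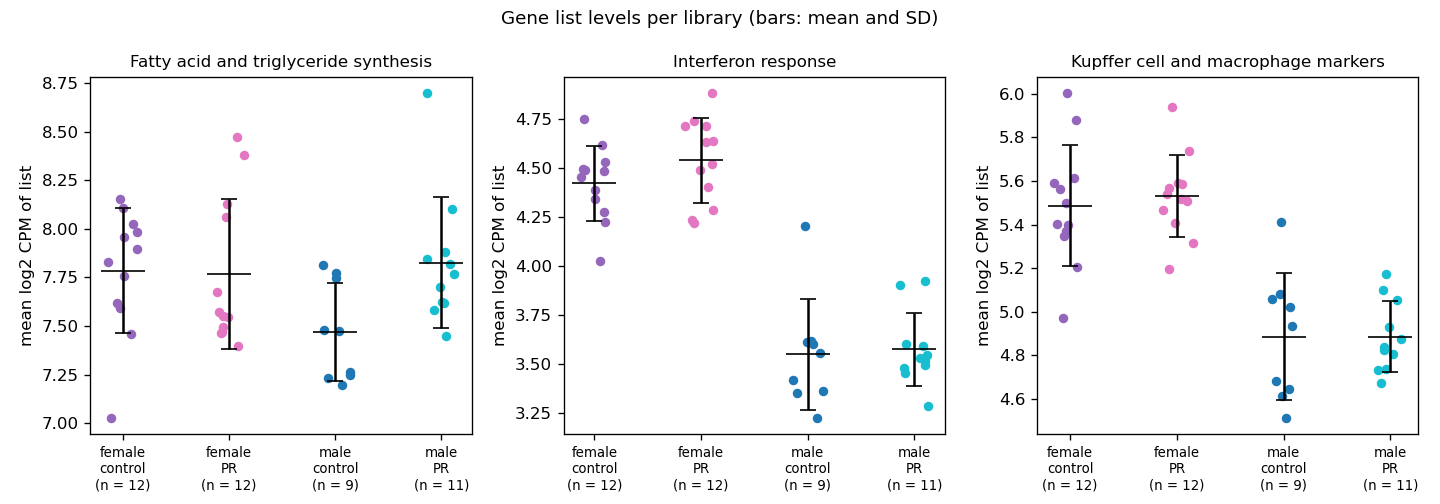
Each point is 1 library, placed at the mean log2 CPM of the tested members of the list named above its panel, with horizontal bars at the group mean and whiskers of 1 SD. The interferon panel shows control females at 4.42 and control males at 3.55 on average.

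Averaged over the sexes, no transcript rose or fell with the diet past the test over all genes. Tcn2, a vitamin B12 carrier (chromosome 11, 3917192 to 3932159), came nearest. It stood at 167 ± 13.1 CPM and 184.8 ± 13.2 CPM in control and PR females and 84.3 ± 6.66 CPM and 92.9 ± 9.63 CPM in control and PR males (SD; log2 change 0.15 ± 0.039 SE, Benjamini-Hochberg adjusted p = 1.000 by edgeR). Slc46a3 had a log2 change of 0.27 ± 0.074, Acss3 of 0.39 ± 0.11, Cyp2j6 of 0.19 ± 0.053 and Med18, a subunit of the Mediator complex, of -0.47 ± 0.12. Over both sexes edgeR's quasi-likelihood test called 0 of 10889 genes, and 446 had an unadjusted p under 0.05 where chance gives 544. DESeq2 and limma-voom also called 0, with 433 and 470. Without number run 9, Acss3 passed here as well (log2 change 0.58, adjusted p = 0.0212 by edgeR). The 95% interval lay within 1.5-fold for 96.7% of genes.

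Of the lists, 11 of 29 passed camera in the averaged comparison, 9 on the higher and 2 on the lower side, and 0 passed with an estimated correlation (smallest adjusted p = 0.583). Fatty acid synthesis (median 0.18, adjusted p = 1.68e-06), oxidative phosphorylation (0.035, adjusted p = 1.68e-06) and the urea cycle list (0.056, adjusted p = 0.000238) were on the higher side. So were PPAR alpha targets (0.037), cholesterol synthesis (0.049), xenobiotic metabolism (0.058), interferon response (0.092), pericentral markers (0.078) and female-biased genes (0.21 over the 16 members with more than 3 counts in every group). Without PR male 240 the female-biased list (median over all tested members 0.14, against 0.37 with it) and the interferon list (0.062) no longer passed. Ribosomal proteins (-0.037, adjusted p = 2.6e-05) and endoplasmic reticulum stress (-0.070, adjusted p = 0.00259) were on the lower side. Within the lists, Acot2, an acyl-CoA thioesterase, had a log2 change of 0.38 ± 0.13, Cyp4a10, a fatty acid hydroxylase, 0.45 ± 0.20, Ehhadh 0.12 ± 0.053 and Sdha, of complex II, 0.064 ± 0.030. In the xenobiotic list Gsta2 was at 0.42 ± 0.15 and Gstp1 at -0.14 ± 0.058, both from families whose members share reads. The leading ribosomal protein genes were Rpl14 (-0.099 ± 0.048) and Rps19 (-0.11 ± 0.061). Of RNA polymerase I and ribosome biogenesis, Utp20 was at 0.13 ± 0.056 and Npm1 at -0.097 ± 0.047, on opposite sides of zero. Adjusted over the list alone, 1 member passed in each of 3 lists and 0 over all genes: Shmt2 (log2 change 0.13 ± 0.039, adjusted p = 0.0366), Gstm2 (0.35 ± 0.10, adjusted p = 0.0415) and Rhbg (0.38 ± 0.12, adjusted p = 0.0357). Again the adjustment did not correct across the 29 lists. Shuffled diet labels gave at least 11 lists in 7 of 60 splits, the real one included, and without number run 1 the count was 3. Without that run the median was 0.015 for ribosomal proteins, on the other side of zero, and 0.00068 for the interferon list.

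Whether the sexes responded differently to the diet was tested as an interaction, the change in males minus the change in females. No transcript passed. Tgm1, a transglutaminase gene (chromosome 14, 55700009 to 55713926), came nearest: it stood at 26.7 ± 7.23 CPM and 18.8 ± 6.41 CPM in control and PR females and at 8.74 ± 3.21 CPM and 12.9 ± 3.96 CPM in males (SD; interaction 1.04 ± 0.27 SE on the log2 scale, Benjamini-Hochberg adjusted p = 1.000 by edgeR). Eif4e, the cap-binding translation factor, had an interaction of 0.33 ± 0.088 and Atf4, a transcription factor induced by amino acid shortage, of 0.31 ± 0.11. Over all genes edgeR's quasi-likelihood test called 0 of 10889 genes, and 370 had an unadjusted p under 0.05 where chance gives 544. DESeq2 and limma-voom also called 0, with 341 and 344. The diet changes of females and males had the same sign in 52.1% of tested genes, and their correlation across genes, which are not independent replicates, was 0.0094.

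The interaction of the fatty acid synthesis list was above zero for 22 of 23 members (median 0.37, camera adjusted p = 9.44e-07, and adjusted p = 0.673 with an estimated correlation). Among them were Thrsp (0.97 ± 0.49), Elovl6 (0.77 ± 0.41) and the stearoyl-CoA desaturase gene Scd1 (0.65 ± 0.38). With shuffled diet labels the interaction median of this list reached -0.54 and 0.46, each larger in size than the real 0.37. Positive medians were also called for RNA polymerase I and ribosome biogenesis (30 of 36 members above zero, median 0.089, adjusted p = 0.00774, and adjusted p = 0.681 with an estimated correlation). Rrn3, an initiation factor of RNA polymerase I, was at 0.36 ± 0.16. The interaction was also positive for ribosomal proteins (60 of 73 members above zero, median 0.047, adjusted p = 0.0212, and adjusted p = 0.794 with an estimated correlation). The cholesterol list had 19 of 25 members above zero, median 0.092, adjusted p = 0.0247, and adjusted p = 0.794 with an estimated correlation. Female-biased genes had a median of 0.53, and of 0.29 over the 16 members with more than 3 counts in every group (adjusted p = 0.0212, and adjusted p = 0.794 with an estimated correlation). Without PR male 240 the female-biased list (median 0.13) and the cholesterol list (0.066) no longer passed. Without the 2 males lying farthest from the others on the first residual component, neither did ribosomal proteins (median 0.017) nor the cholesterol list (0.093). Pericentral markers went the other way, 13 of 15 members below zero, median -0.11, adjusted p = 0.00230, and adjusted p = 0.673 with an estimated correlation. Slc1a2, a glutamate transporter, was at -0.31 ± 0.14. In shuffled diet labels, 43 of 60 splits gave at least 6 lists.

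**Figure D2:**
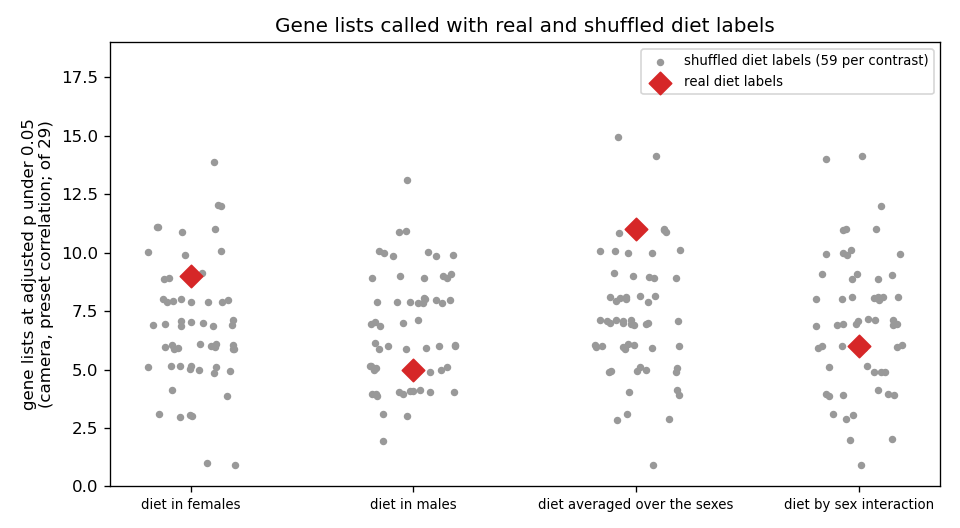
The vertical axis gives the number of gene lists that passed camera with its preset correlation in each diet comparison on the horizontal axis, with grey points for shuffled diet labels, shifted slightly to keep them apart, and red diamonds for the real labels. The real labels gave 9, 5, 11 and 6 lists, each within the range of the shuffles.

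Sex set the control livers apart: 2706 of 10889 genes differed between control males (n = 9) and control females (n = 12), 1259 higher in males and 1447 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 354 differed by over 2-fold. The genes of sex-specific liver metabolism led. Cyp2d9, a male-specific cytochrome P450 (chromosome 15, 82433437 to 82456845), stood at 1499 ± 208.7 CPM in males and 34.9 ± 10.05 CPM in females (SD), a log2 change of 5.44 ± 0.16 (SE). Mup20, a major urinary protein, stood at 5381 ± 1073 CPM and 133 ± 43.6 CPM (5.33 ± 0.17). Gstp1, a glutathione transferase (chromosome 19, 4035407 to 4037985), stood at 969 ± 138 CPM and 114 ± 20.2 CPM (3.08 ± 0.086). C6, of the terminal complement complex, stood at 365 ± 56.6 CPM and 33.1 ± 7.15 CPM (3.46 ± 0.12). In the other direction Cyp2b9 stood at 0.955 ± 1.44 CPM in males and 599 ± 96.5 CPM in females, and Cyp2a4 at 0.349 ± 0.374 CPM and 869.9 ± 197.01 CPM. Cyp2c40 stood at 6.25 ± 4.80 CPM and 500.3 ± 106 CPM, and Slc22a26, an organic anion transporter gene, at 0.238 ± 0.314 CPM and 191.4 ± 37.7 CPM. Nt5e, the ecto-enzyme that makes adenosine, was lower in males, at 13.8 ± 2.55 CPM against 148 ± 25.7 CPM (log2 change -3.43 ± 0.12), and Fmo1, a flavin mono-oxygenase, at 135 ± 9.44 CPM against 327 ± 34.5 CPM (-1.28 ± 0.059). Of the male-biased list, 19 of 19 members were higher in males over all genes, and 19 when adjusted over the list alone. Of the female-biased list, 21 of 22 were lower over all genes and 21 over the list alone, while Adam11 was higher in males (4.15 ± 1.65 CPM against 2.58 ± 1.26 CPM). Both lists held with an estimated correlation (adjusted p = 3.09e-12 and 6.82e-11). Members of the Cyp2a, Cyp2c, Cyp2d, Cyp4a, Gstp and Mup families resemble each other closely, so reads could have been divided among them and single members are uncertain. The count was 1791 with counts summed per number run, and 1796 without number run 1.

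Markers of several non-hepatocyte cell types fell in males together. Of the Kupffer cell and macrophage markers, 13 of 14 were lower over all genes and 13 when adjusted over the list alone (median log2 change -0.66, camera adjusted p = 1.3e-06, and adjusted p = 0.303 with an estimated correlation). Vsig4, a complement receptor of Kupffer cells, measured 53.1 ± 10.2 CPM in females and 27.8 ± 5.41 CPM in males (-0.96 ± 0.12). Ctss (-0.71 ± 0.10), C1qa (-0.69 ± 0.11) and C1qc (-0.69 ± 0.10) fell alike. Of stellate cell and fibroblast markers, 7 of 15 fell (8 over the list alone; median -0.37, adjusted p = 0.00708, and adjusted p = 0.303 with an estimated correlation). Dcn, decorin (-0.37 ± 0.054), was among them, as was Col14a1 (-0.40 ± 0.075). Of endothelial markers, 7 of 15 fell (7 over the list alone; median -0.21, adjusted p = 0.0122, and adjusted p = 0.325 with an estimated correlation). Clec4g (-0.40 ± 0.073) and Kdr (-0.28 ± 0.061) were 2 of these. The interferon response list fell further: 19 of 23 members were lower in males over all genes and 19 over the list alone (median -0.88, adjusted p = 4.93e-12, and adjusted p = 0.0647 with an estimated correlation). Guanylate-binding protein genes led it, Gbp3 at 38.9 ± 10.2 CPM and 9.07 ± 1.68 CPM (-2.12 ± 0.18), Gbp2 (-1.68 ± 0.15) and Gbp7 (-1.34 ± 0.15), with Ifi44 at -1.89 ± 0.21. Over all 29 lists, 10 passed camera and 2 with an estimated correlation. Shuffles of the sex labels among the control libraries gave as many lists in 23 of 60 splits, while the most genes called in a split other than the real one were 8.31% of the real count. Splits with unequal shares of the sexes carried part of the sex difference, so these counts are not those of libraries without one.

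Cholesterol synthesis and uptake genes were lower in males, 13 of 25 over all genes and 15 over the list alone, with all 25 below zero (median -0.38, camera adjusted p = 0.00180, and adjusted p = 0.814 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, measured 1096 ± 381 CPM in females and 624 ± 178.9 CPM in males (-0.81 ± 0.22). Genes of endoplasmic reticulum stress were higher in males, 10 of 19 over all genes and 13 over the list alone (median 0.37, adjusted p = 0.00300, and adjusted p = 0.814 with an estimated correlation). They included Derl3 (2.87 ± 0.62), Sdf2l1 (1.07 ± 0.25), Dnajb11 (0.52 ± 0.14) and Pdia6 (0.48 ± 0.13). In the growth hormone and IGF list, 5 of 15 genes fell and 2 rose, with the same counts over the list alone (median -0.12, adjusted p = 0.0445, and adjusted p = 0.303 with an estimated correlation). Prlr, the prolactin receptor, measured 374 ± 59.7 CPM in females and 80.1 ± 31.8 CPM in males (-2.23 ± 0.17), Socs2, a feedback inhibitor of growth hormone signalling, 66.1 ± 44.1 CPM and 14.9 ± 7.43 CPM (-2.20 ± 0.39), and Igfals fell by 0.65 on the log2 scale. Periportal markers were mixed: 6 of 13 fell, led by Ctsc (-1.50 ± 0.084) and Aldh1b1 (-1.37 ± 0.15), while Cyp2f2 (0.72 ± 0.084) and Hsd17b13 (0.28 ± 0.056) rose. Over the list alone 7 fell and 2 rose (camera adjusted p = 0.0195, and adjusted p = 0.325 with an estimated correlation). Without number run 5, Hmgcs1 (log2 change -0.68, adjusted p = 0.0888), Dnajb11 (log2 change 0.38, adjusted p = 0.115) and Pdia6 (log2 change 0.38, adjusted p = 0.0902) no longer passed. With counts summed per run and sex, Sdf2l1 did not (log2 change 1.11, adjusted p = 0.05003).

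The sex difference was much alike in PR mice, a comparison added after the data were seen. There 3005 genes differed, 1459 higher and 1546 lower in males. Of the 2706 genes called in controls, 1969 were also called in PR mice in the same direction and 0 in the opposite one, where independent lists would share 374. Cyp2d9, for example, stood at 1466 ± 145 CPM in PR males and 35.2 ± 12.9 CPM in PR females, and Cyp2b9 at 2.09 ± 3.25 CPM and 612 ± 118 CPM. The interferon response list was lower here too, with 22 of 23 members called (median log2 change -1.11, camera adjusted p = 3.93e-16, and adjusted p = 0.0203 with an estimated correlation). Lower as well were 13 of 14 Kupffer cell markers (median -0.66, adjusted p = 0.198 with an estimated correlation). Shuffled sex labels gave at most 76 genes in 40 splits, the real one aside. No library was common to both comparisons.

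**Figure D3:**
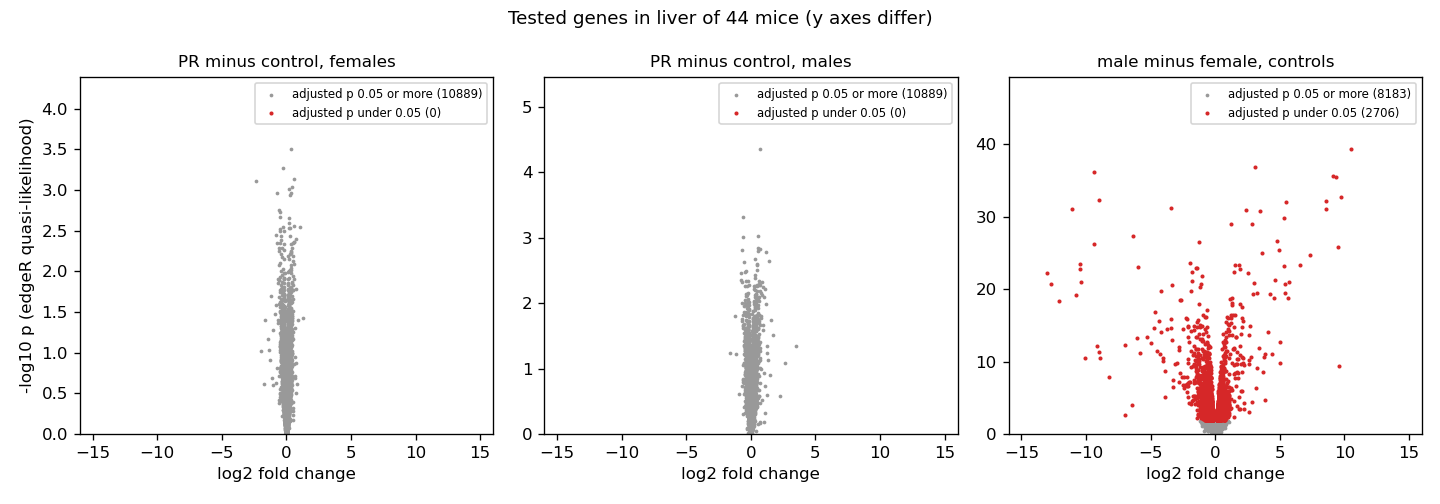
Each point is 1 tested gene, with its log2 fold change on the horizontal axis and minus log10 of its p on the vertical axis, which differs between panels, and red marks an adjusted p under 0.05. The diet panels hold 0 red points each and the sex panel 2706.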

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

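The tests of composition scores as covariates, of the runs of sample numbers and of shuffled sex labels were chosen after the results were seen, and the sex shuffles were redrawn once their first results were known; bootstrap intervals and their rule were also added then. In the group of 9 control males, the one small enough for Dixon's test, 6 of 60 values stood far from the other males, where chance gives 3, about 1 in 20. The interferon response score of 1 male of number run 5 was 4.204 (median of the group 3.56), and its Rgs5 level 33.6 CPM (median 18.6 CPM). A male of number run 1 had a stellate cell score of 4.32 (median 4.70), and another of that run had 83.3 CPM of Aldh1b1 (median 56.6 CPM). Another male of number run 5 had 1.12 CPM of Cyp2a4 (median 0.279 CPM) and 47.1 CPM of Cyp4a12b (median 29.1 CPM). Its Cyp2a4 value lay near the counting floor, as the library held 1784293 counts in all, so Dixon's test says little about it. In 6 lists the diet change differed between males and females by camera with its preset correlation: fatty acid synthesis (median difference 0.37), female-biased genes (0.53), cholesterol synthesis (0.092), RNA polymerase I and ribosome biogenesis (0.089), ribosomal proteins (0.047) and pericentral markers (-0.11). None of them passed with an estimated correlation, and female-biased genes and cholesterol synthesis did not pass without PR male 240.

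Fatty acid synthesis genes lay higher in PR males than in control males. The composition score of a library was its score on the first component of variation within groups, 11.4% of the variance. The tables argue against that component as the whole reason, since 1.04 of the list's median change stayed with the score as a covariate (bootstrap interval 0.83 to 1.12). Control and PR males spread more along the second component (SD 13.4 and 10.3, against 8.68 and 6.90 on the first). Other differences in library composition were not tested for this list. Clock phase cannot be told apart from the diet here, because 0.91 of the change stayed with the clock score but the bootstrap interval ran from 0.50 to 1.09. A grouping of the males by chance stays open as well: 4 of 60 splits, the real one included, gave a median as large in either direction (0.30 with the real labels, and 0.34, -0.35 and -0.36 in the others). The diet itself, litter and feeding state remain untested.

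The first component of variation within groups, 11.4% of the variance, separated the females of number runs 1, 2, 3 and 5 (scores -19.1 to -0.805) from those of runs 4, 8, 9 and 10 (5.27 to 29.8), each with 6 control and 6 PR mice. Depth does not account for it as a whole, since the slope of the scores after thinning to equal totals on those before was 0.93 (0.91 to 0.94), although score and total had a Spearman rho of -0.70. Trends with GC content and transcript length do not either, with a slope of 0.78 after their removal (0.77 to 0.80). Runs of sample numbers go with it, though not in numerical order, as run 5 lay with the earlier runs and run 4 with the later ones: 84.0% of the score's variance lay between runs (permutation p = 0.0001, the smallest possible). Males did not divide alike, with scores of -14.3 to 18.6 in runs 1, 2, 3 and 5 and -0.667 to 16.7 in runs 8 and 9. But runs 8 and 9 held only 1 and 3 males, and runs 4 and 10 held none. Both upper ends were the outlying male libraries (986261 and 1717933 counts). With so few males, these scores cannot decide on a cause shared by both sexes of a run, such as litter or age. Small nucleolar RNAs divided the females as well, with 331 to 445 CPM in runs 1, 2, 3 and 5 and 209 to 286 CPM in the others. Males of all runs lay at 220 to 326 CPM. Xist ranged over 364 to 707 CPM and 504 to 1211 CPM in the same 2 sets of females. No such shared cause, no cause of the small RNA difference and no biological explanation was tested.

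Kupffer cell markers and interferon response genes were lower in control males than in control females. The tables argue against a smaller share of all non-hepatocyte RNA as the whole reason, since the Kupffer score differed by -0.60 and the endothelial score by -0.21 (exact permutation p of the difference = 0.0113), while against the stellate score (-0.32) the exact permutation p was 0.0902. They argue against the first component of variation within groups too, with 1.02 of the interferon median kept when its score was a covariate. Other differences in library composition were not tested. Whether fewer macrophages account for the interferon difference cannot be told apart from a change within cells, because 0.77 of it stayed with the Kupffer score as a covariate, with a bootstrap interval of 0.55 to 0.97. A difference between the sexes was what this contrast tested, and through what it acts stays open.

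Counts of called genes and lists were set against shuffled labels. The diet comparisons called 0 genes, so all 60 of 60 splits gave as many, and the highest other split called 10 genes in females, 1 in males, 12 averaged and 0 for the interaction. As many lists were called in 15, 47, 7 and 43 of 60 splits (real 9, 5, 11 and 6; highest other 14, 13, 15 and 14). When the 8 female runs were divided into 4 and 4, 8 of 35 splits gave as many lists as diet (highest other 14), and 9 of the other splits called genes. The most, 2513, came from runs 1, 2, 3 and 5 against 4, 8, 9 and 10, a division that follows the first component. For sex in controls, 1 of 60 splits, the real one, called 2706 genes (the highest other called 8.31% as many), but 23 splits gave as many as 10 lists (highest other 15). Because the shuffled libraries differed by sex, the list count cannot tell whether the sex lists were called by chance. For sex in PR mice, 1 of 40, the real one, called 3005 genes (highest other 76).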

How the results depend on the processing

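Alternatives chosen after the data were seen were the female library sets, the first component as a covariate, the omission of 2 outlying males, of PR male 240 (the PR male with the most Xist counts), and of each run for lists. No sample number occurs in 2 groups, but 6 runs held both sexes, and limma-voom with the run as a random block called 2848 genes for sex in controls. No diet comparison called a gene under any alternative except without number run 9, where 1 was called in males and 1 averaged; leaving out each run gave 0 to 1 and 0 to 1. Sex in controls called 1796 to 2807 genes when each run was left out and 1791 with counts summed per run and sex, both with fewer samples; upper quartile scaling gave 969 higher and 1742 lower (35.7% higher) against 1259 and 1447 (46.5%). Of 53 genes named for sex, 7 missed the threshold in some alternative, and 0 changed direction. Lists passing camera ranged over 3 to 10 in females, 3 to 13 in males, 3 to 16 averaged, 4 to 8 for the interaction and 9 to 14 for sex when each run was left out, and 8 passed in males and 4 for the interaction without the 2 outlying males (986261 and 1717933 counts). Without PR male 240, 3 lists passed in males, 10 averaged and 5 for the interaction, and the female-biased list passed in none of these 3 (medians 0.27, 0.14 and 0.13). With an estimated correlation 0, 0, 0, 0 and 2 passed, and with fry and the run as a random block 0, 0, 0, 0 and 14. The direction of the camera test turned in the females of number runs 1, 2, 3 and 5 for the urea cycle list (median -0.045), oxidative phosphorylation (-0.0062) and periportal markers (-0.12), and in those of runs 4, 8, 9 and 10 for cholesterol synthesis (-0.094) and PPAR alpha targets (-0.065). When each run was left out, list medians spanned, in females, ribosomal proteins -0.11 to -0.0038, the urea cycle list 0.014 to 0.11, cholesterol synthesis -0.069 to 0.049, PPAR alpha targets 0.023 to 0.14, oxidative phosphorylation -0.021 to 0.063 and periportal markers -0.038 to 0.039. In males they spanned ribosomal proteins -0.056 to 0.024, acute phase genes -0.23 to 0.084 and Kupffer cell markers -0.14 to 0.11, and averaged ribosomal proteins -0.072 to 0.015, interferon response 0.00068 to 0.15 and Kupffer cell markers -0.099 to 0.14. Of these, the direction of the camera test turned, with the medians given, without run 1 for ribosomal proteins (-0.0038 in females, 0.024 in males, 0.015 averaged) and the averaged interferon list (0.00068), without run 5 for acute phase genes (0.084) and Kupffer markers (0.11) in males, without run 9 for averaged Kupffer markers (-0.099) and without run 10 for oxidative phosphorylation in females (-0.021); the cause was not tested. With these totals, group sizes and spreads between mice a 1.5-fold change was recovered for 70% of simulated genes in females and 64% in males. That simulation changed many genes at once and held no effect of run, so it does not give the recovery of a lone changed gene. How much of the recovery is due to depth was not tested.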

Other observations

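The test of Arntl against Dbp was chosen after their levels were seen, and the test of spread before. Several groups of liver genes that the report does not describe showed no camera call with diet. The DNA methylation machinery, of interest in a study of inheritance, had a median log2 change of -0.043 in PR females (adjusted p = 0.343) and -0.032 in PR males (adjusted p = 0.985). Genes of gluconeogenesis and fasting had medians of 0.10 and 0.076 (adjusted p = 0.255 and 0.205), and glucocorticoid response genes 0.011 and -0.18 (adjusted p = 0.975 and 0.205).

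Clock genes differed in how far they ranged over the libraries. Dbp, a clock output gene, ranged from 1.69 to 85.0 CPM, Arntl, the core activator, from 4.29 to 50.1 CPM, and Per1 from 0.831 to 42.4 CPM. Nr1d1, a clock repressor, had a narrower range, 17.5 to 58.7 CPM. After group means were removed, Arntl and Dbp had a Pearson r of -0.79 and a Spearman rho of -0.77 (permutation p = 1e-05 for both, the smallest possible). Without the 2 libraries farthest from the median of Arntl, r was -0.78. A difference in time of day or feeding between mice may lie behind this opposite movement, a hypothesis the correlation fits but that the labels, which give no time of collection, leave open.

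A hypothesis that the diet raises the spread between mice was tested on the variance of log2 CPM. The median log2 ratio of PR to control variance was -0.097 in females (one-sided permutation p = 0.694) and -0.16 in males (p = 0.756). Shuffled labels gave -0.36 to 0.34 and -0.44 to 0.49 (central 95%), so the bound set beforehand, which took a missed threshold as evidence against the hypothesis, was wrong, and these values leave it open. In PR males Xist reached 22 counts in the library numbered 240, against 3 at most in control males, and the call of the female-biased list in PR males was lost without it.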
